A study of Homo sapiens with 8 samples.

How the data were processed

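The samples were 8 libraries of Okazaki fragments (genomic DNA) from hTERT RPE-1 cells, 4 groups of 2 replicates. Per the labels, untreated cells were pulsed with EdU for 2 min and cells in 0.2 mM HU for 4 min, at an EdU concentration given there as 20 mM; the HU groups had control, FANCI or FANCD2 siRNA. HU and pulse length therefore cannot be separated, and no untreated cells with FANCI or FANCD2 siRNA were analysed here. The series' stated aim was to map replication initiation and termination.

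Per the submitters' processing notes the build was hg19 and Bowtie2, SAMtools, Picard and bedtools were used, without versions or roles. The deposited files of each library hold a signal, the mean read coverage per base in 1 kb bins on the Watson and the Crick strand of the 22 autosomes, not scaled for depth. This was checked on the values: 29.1 to 61.2% of them per library were whole multiples of 0.051, what a read of 51 bases adds to a bin of 1000 bases, and the others lay between, as a read across a bin edge adds less. Coverage was turned into read equivalents (coverage times 1000 over 51). The gene tables of the authors list 17920 genes with an FPKM column and a DRIP-seq (DNA-RNA hybrid) signal around the TSS. Both columns are the same in all 8 tables and so measure none of these libraries; the RNA and DRIP data they come from are not given in the sources used here. Of these genes 4161 have FPKM 0, 618 have no FPKM, and 24 have symbols turned into dates by a spreadsheet, which were tested but not named. The files do not say which strand belongs to which fork direction. Crick reads were taken as rightward forks, as is usual for this method, and under this choice shares rise at the TSS of transcribed genes.

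Depth, in M read equivalents, was 26.3 and 59.4 in untreated cells, 79.6 and 52.4 in HU with control siRNA, 40.9 and 89.9 with FANCI siRNA, and 84.5 and 85.3 with FANCD2 siRNA. The median bin held 9.0 to 29.4 reads, and 50.0 to 50.1% of reads were on the Crick strand.

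Genes of 10 kb or more (12033) with a mean of 20 or more reads per window were tested, 11943 for the TSS step, 11940 for the end step, 11954 for the direction at the end and 11996 for the count. Windows were 10 kb on each side of the TSS or gene end. The step is the log2 odds of co-directional over head-on reads after the site minus that before it; the direction is the log2 odds in the last 10 kb of the gene; the count is log2 reads over the gene, centred on the median gene. To every number of reads 0.5 was added. The plan fixed before the data were examined was a test for counts. The values proved to be coverage, so limma's moderated test (empirical Bayes with a trend on the counting precision) was used on these log2 values, with all 8 libraries in a fit of 4 group means and Benjamini-Hochberg adjustment per comparison at 0.05. For the count limma pooled the spread fully over genes of the same precision. Comparisons were HU against untreated (both control siRNA), FANCI and FANCD2 siRNA against control siRNA (all with HU), and FANCI against FANCD2 siRNA.

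Mean shares and steps per library were compared by exact permutation of the libraries. With 2 against 2 (6 splits) the smallest p is 0.333 and with 6 HU libraries against 2 untreated (28 splits) 0.0357. These exact p-values were not adjusted for the number of shares and steps compared. Random sites of the series (17920) were measured in the same way. FPKM quartiles ended at 0.0235, 2.43 and 7.91 and length quartiles at 19.7, 36.8 and 77.9 kb. Lists fixed beforehand were tested by limma's fry (its directional p, which asks whether the list itself shifts and does not compare it with other genes) and by camera, with a preset correlation of 0.01 and with an estimated one, adjusted over 28 tests per measure. WWOX and MYC, also chosen beforehand, were not tested.

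Genes were named by a rule fixed before the data were examined. Among genes past the threshold whose libraries do not overlap between groups, these were the 3 largest rises and 3 largest falls per measure and comparison, at most 1 per 500 kb because neighbours share forks. Where none passed, the gene with the smallest p was given as a value. Added were up to 4 members of each list with the smallest p in the HU comparison, and FHIT and LMNB2. Olfactory receptor genes, pseudogenes and uncharacterised loci were not named. Other genes are marked where they stand. Some genes that the rule takes are not reported here.

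Replicate numbers make only 2 pairs per comparison and no label gives a shared batch, so libraries were not paired. Alternatives fixed beforehand covered the replicate block, read minimum, groups in the fit, leaving out each library, gene length, depth thinned to the smallest library, window width, strand totals, region and set test. Count scaling to total coverage, weights, a fit with no variance trend, masked bins and crossed replicate numbers were added after seeing the data.

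The method was tested on simulated data with the real depths, in which 200 genes were changed. Every gene got the same extra spread, the median of the real data, drawn independently. Genes of larger spread and neighbours that share forks were thus not simulated. For HU against untreated a log2 change of 2 was recovered in 86.4% of genes for the TSS step, 86.4% for the end step, 89.4% for the direction and 100% for the count, a change of 1 in 16.4, 38.8, 19.4 and 100%, and a change of 0.5 in 1.5, 4.5, 1.5 and 50.7%. For FANCI siRNA a change of 2 was recovered in 89.4, 92.4, 97 and 100% and for FANCD2 siRNA in 78.8, 93.9, 98.5 and 100%. A change of 1 was recovered in 13.4, 19.4, 20.9 and 100% for FANCI siRNA and in 14.9, 16.4, 31.3 and 100% for FANCD2 siRNA. Among unchanged genes, 12 were called for the count with FANCI siRNA, 14 with FANCD2 siRNA and 6 for FANCI against FANCD2 siRNA. Smaller changes of steps and direction can thus be missed. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.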

Results

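Okazaki fragments were mapped by strand in hTERT RPE-1 cells to follow where replication forks start and end. There were 4 groups of 2 libraries: untreated cells with control siRNA, and cells given 0.2 mM hydroxyurea (HU), which lowers nucleotide pools and slows forks, with control siRNA, FANCI siRNA or FANCD2 siRNA. FANCI and FANCD2 are the partners of the Fanconi anaemia complex that acts at stalled forks and DNA crosslinks. Each gene was described by the co-directional share, the percent of fragments from forks that moved in the direction of transcription. A rise of that share across a site (a positive step) means net initiation there, and a drop (a negative step) means net termination. Genomic DNA holds no measure of siRNA knockdown, so FANCI and FANCD2 levels were not known here.

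In untreated cells, forks moved away from transcription start sites (TSS) into the gene. Over genes of 10 kb or more the share was 53.4 ± 0.189% in the 10 kb before the TSS and 61.5 ± 1.48% in the 10 kb after it (mean ± SD of 2 libraries), a step of 8.06 ± 1.67 percentage points. At gene ends it went down, from 52.9 ± 2.11% in the last 10 kb of the gene to 48.6 ± 0.561% in the 10 kb after it, a step of -4.26 ± 1.54 points. The TSS step grew with transcription: it was 3.30 ± 1.35 points in the quartile of genes of lowest FPKM and 11.3 ± 2.05 points in the highest. In genes of 100 kb or more in the upper FPKM quartiles 3 and 4 (997 genes), the share was 76.8 ± 0.126% in the first of 10 equal parts of the gene and 46.1 ± 3.55% in the last. At random sites it was 49.6% in untreated cells on the upstream side.

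**Figure D1:**
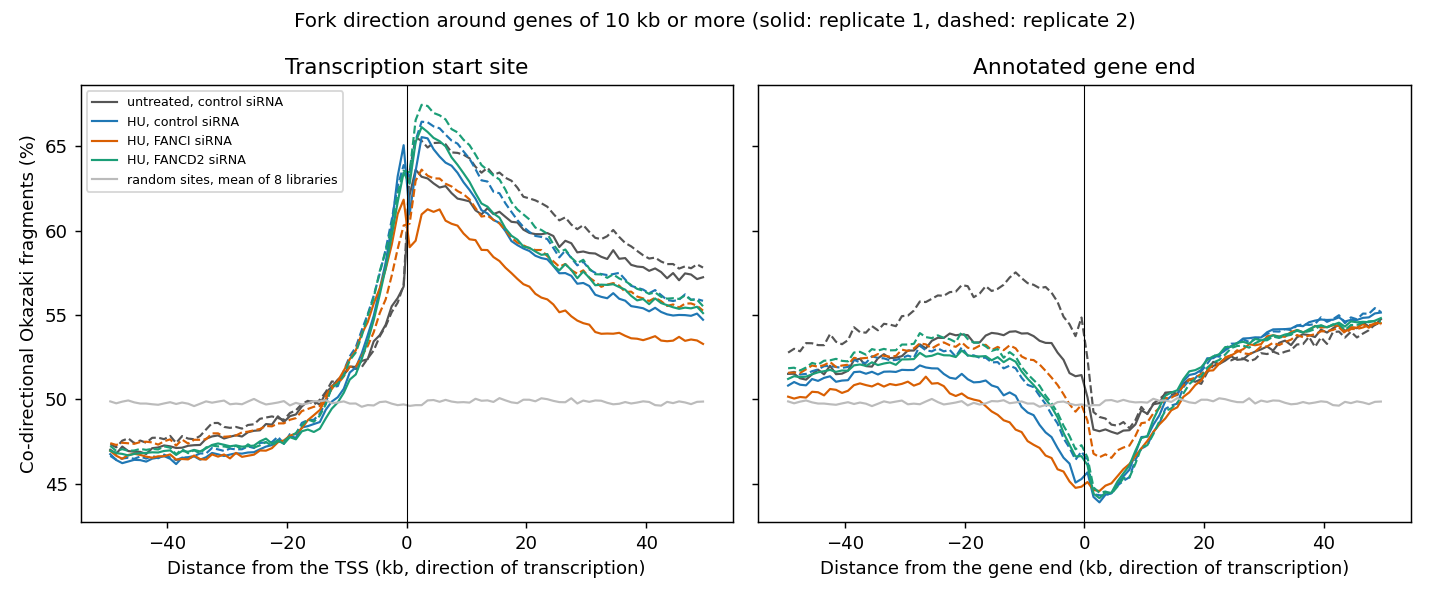
Percent of co-directional fragments (y axis) against distance in kb from the TSS and from the gene end (x axis) over genes of 10 kb or more, with replicate 1 solid, replicate 2 dashed, groups by colour and random sites in grey. In the kb before the TSS the share was 56.7 ± 0.0622% in untreated cells and 64.5 ± 0.835% in HU with control siRNA, and from 1 to 10 kb after the gene end 48.5 ± 0.355% and 45.2 ± 0.0997% (mean ± SD).

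With HU, initiation close to the TSS moved in both directions at single genes. At KANSL2, a subunit of the NSL histone acetyltransferase complex (chromosome 12, 49046995 to 49076008), the step rose by 3.16 (log2 odds ratio, SE 0.49, adjusted p = 0.0139). It had 65.9% co-directional forks before the TSS and 97.7% after it, against 83.8% and 92.3% in untreated cells. CSE1L, the export receptor of importin alpha (chromosome 20, 47662783 to 47713497), rose by 2.53 (SE 0.38, adjusted p = 0.0139) and the matrix metalloprotease gene MMP2 (chromosome 16, 55513081 to 55540586) by 2.45 (SE 0.39, adjusted p = 0.0139). At MMP2 the share after the TSS was 94.6% with HU and 81.2% without. The step fell at NETO2 (-3.08, SE 0.77, adjusted p = 0.0453), an auxiliary subunit of kainate receptors, at ZNF117 (-2.92, SE 0.60, adjusted p = 0.026) and at FBXO8 (-2.76, SE 0.68, adjusted p = 0.0444). Before the TSS of NETO2 the share was 25.5% with HU and 10.8% without, and after it 38.6% and 63.5%. In these genes both HU libraries lay on the same side of both untreated libraries.

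Of 11943 genes tested for the TSS step by limma, 145 rose and 132 fell with HU. By FPKM quartile, 62 rose and 36 fell in the highest and 9 rose and 9 fell in the lowest. Among 50 replication and DNA damage response genes, FANCI rose (1.94, SE 0.41, adjusted p = 0.0304) and POLD1, the catalytic subunit of DNA polymerase delta, fell (-1.59, SE 0.39, adjusted p = 0.0444). The other 48 did not pass. Adjusted over the list alone, 9 of the 50 passed. Of the 38 mesenchymal and cytoskeletal genes 1 passed, the actin-binding CALD1 (1.96, SE 0.47, adjusted p = 0.0419; 1 passed over the list alone). Of the 30 housekeeping genes 1 passed, the translation factor EIF4G1 (1.52, SE 0.33, adjusted p = 0.0343; 1 over the list alone). Of the 33 genes restricted to blood, liver or muscle the urea cycle gene CPS1 fell (-2.25, SE 0.55, adjusted p = 0.0445; 5 over the list alone). Of the 29 genes of common fragile sites 0 passed with limma (3 at an unadjusted p under 0.05; 0 over the list alone), with a median of 0.02 and a mean of -0.07. FHIT, a large fragile-site gene, had -1.23 (SE 0.36, adjusted p = 0.0749). Of the 10 genes at classical replication origins 0 passed (3 unadjusted; HSPA4 over the list alone), and LMNB2, whose end holds a mapped human origin, had 0.19 (SE 0.43, adjusted p = 0.845). Genes of 300 kb or more gave 7 rises and 2 falls of 479 (6 over the list alone), among them WDR70 (1.97, SE 0.40, adjusted p = 0.0246) and ABCA13 (-1.91, SE 0.36, adjusted p = 0.0195).

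Across all genes the mean TSS step was 6.09 ± 0.390 points in HU with control siRNA, a difference from untreated of -1.97 ± 1.21 points (difference ± SE). The share before the TSS differed by 2.18 ± 0.551 points and that after it by 0.207 ± 1.32 points. The smaller step thus came with a higher share before the TSS and does not show less initiation around it. From 10 to 20 kb before the TSS the share pooled over genes was 50.1% untreated and 49.2% in HU with control siRNA. From 1 to 10 kb after it the pooled shares were 63.8% and 65.0%, so the wider mean rise was not smaller with HU (not tested). With 2 libraries against 2, an exact permutation test cannot give p below 0.333, which the upstream share and the step reached. Over all 6 HU libraries against the 2 untreated, the upstream share was higher by 1.85 ± 0.309 points (exact p = 0.0357, unadjusted and the smallest possible). This share was higher in 6 of 6 HU libraries. The step differed by -1.93 ± 1.32 points (exact p = 0.25). The upstream difference was 0.792 points with 20 kb windows (exact p = 0.107), and with 5 kb windows the step difference was -3.45 points (exact p = 0.0357). The 277 gene calls became 0 without either library of HU with control siRNA, 77 without untreated replicate 2, 29 without either FANCD2 siRNA library and 554 without either FANCI siRNA library; 5 kb windows gave 0 and 20 kb windows 1089. With the replicate number as a block 1409 genes passed, and fry passed the lineage-restricted list (median -0.33, adjusted p = 0.00655). By camera, without the block, that list had adjusted p = 0.978 with an estimated correlation.

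At gene ends, forks moving with transcription made up a smaller share with HU. Over all genes the share in the last 10 kb was 52.9 ± 2.11% in untreated cells and 48.1 ± 0.572% in HU with control siRNA, a difference of -4.76 ± 1.54 points. In the genes of lowest FPKM it was 49.5 ± 1.04% and 48.8 ± 0.747%, and in those of highest FPKM 56.0 ± 2.68% and 49.0 ± 0.436%. Examples come from the replication and DNA damage response genes, a list that did not pass fry (adjusted p = 0.202) and passed camera at its preset correlation (adjusted p = 0.0191) but not otherwise (adjusted p = 0.935 with an estimated correlation). BLM, a helicase of recombination intermediates (chromosome 15, 91260579 to 91358686), had 11.9 ± 2.09% co-directional forks at its end with HU and 37.8 ± 0.580% without (log2 odds -2.18, SE 0.28, adjusted p = 0.00316). RAD50, of the MRN double-strand break complex (chromosome 5, 131892616 to 131980313), had 26.2% and 56.3%, and PALB2, the partner of BRCA2 (chromosome 16, 23614483 to 23652678), 22.7% and 54.1%.

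**Figure D2:**
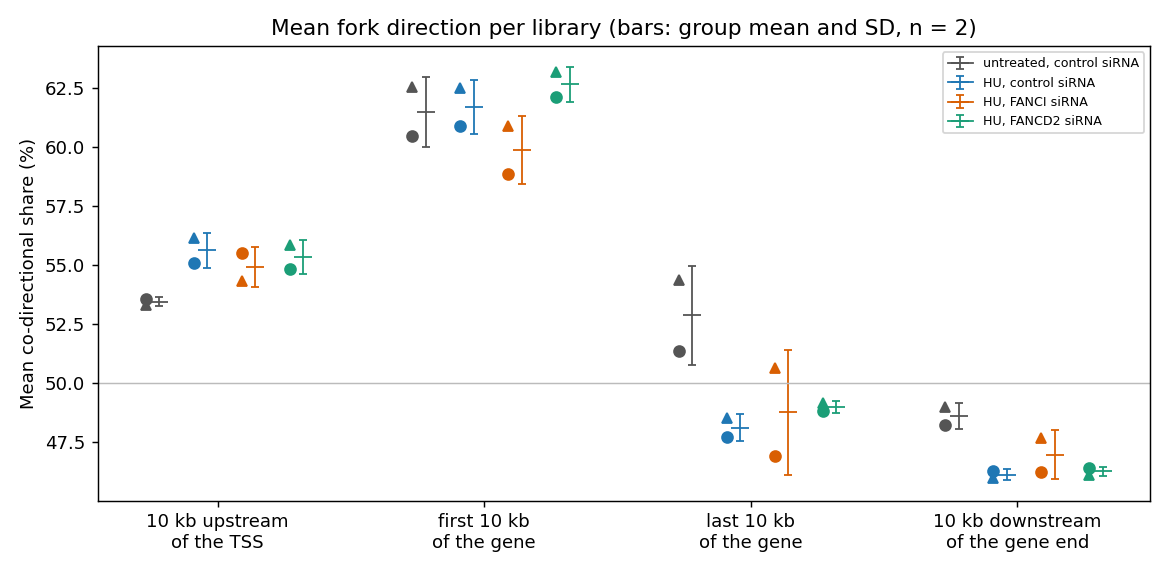
Mean co-directional share in percent (y axis) on either side of the TSS and gene end (x axis) over genes of 10 kb or more, per library (circle, replicate 1; triangle, replicate 2), with group mean and SD (bars). In the last 10 kb of genes the group means were 52.9% untreated, 48.1% in HU with control siRNA, 48.8% with FANCI siRNA and 49.0% with FANCD2 siRNA.

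Of 11954 genes, 217 rose and 1659 fell with HU by limma, with a median log2 change of -0.32. The falls made up 2.78% of the genes of lowest FPKM, 10.56% in the next quartile, 21.43% in the third and 20.83% in the highest, and 7.62% of the shortest and 19.33% of the longest quartile of genes, but 8.06% of genes of 300 kb or more. The largest falls were at NOMO1 (-2.82, SE 0.56, adjusted p = 0.00615), CCZ1 (-2.78, SE 0.73, adjusted p = 0.0197) and USP37, a deubiquitinase that acts in S phase (-2.67, SE 0.39, adjusted p = 0.00316). The end of USP37 (chromosome 2, 219314974 to 219433084) had 26.2% with HU and 69.0% without. NOMO1 and CCZ1 have near-identical copies elsewhere in the genome, so their reads are less certain. The largest rises were at WFDC10B (2.21, SE 0.57, adjusted p = 0.0184), at the tau gene MAPT (2.20, SE 0.36, adjusted p = 0.00369) and at PRG4, the lubricant of joints (2.14, SE 0.51, adjusted p = 0.0146). The end of MAPT (chromosome 17, 43971748 to 44105699) had 89.1% co-directional forks with HU and 64.7% without.

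Of the 50 replication and DNA damage response genes 19 fell and 1 rose (27 passed over the list alone; median -0.82). Besides BLM, RAD50 and PALB2 the falls included RPA1 (-1.39, SE 0.31, adjusted p = 0.0104), the large subunit of the single-strand binding protein. The exception was USP1 (1.14, SE 0.36, adjusted p = 0.0408), the deubiquitinase of FANCD2 and FANCI, named after its value was seen. Of the 38 mesenchymal and cytoskeletal genes 6 fell and 0 rose (7 over the list alone), among them TEAD1 (-1.49), CCND1 (-1.41; 49.1% with HU and 71.9% without) and CD44 (-1.05). Of the 30 housekeeping genes 6 fell, such as TCP1 (-1.23) and COPA (-1.55), and HNRNPU rose (1.08; 7 over the list alone). Of the 29 fragile-site genes 2 fell, NBEA (-1.28) and RORA (-1.51), and 1 rose (3 over the list alone). FHIT had 72.2% with HU and 74.6% without (-0.17, adjusted p = 0.813). Of the 34 lineage-restricted genes SPI1 fell (-0.94, adjusted p = 0.0459) and 0 rose (3 unadjusted; 0 over the list alone), with a median of 0.00 and a mean of -0.02. Of the 10 origin genes MCM4 (-1.59) and AXIN1 (-1.13) fell (2 over the list alone), and LMNB2 had -0.02 (adjusted p = 0.982). Of the 484 genes of 300 kb or more 39 fell and 7 rose (13 over the list alone; median -0.30), with RASAL2 (-2.21; 9.24% with HU and 32.1% without), ZFAND3 (-1.82), SCAPER (-2.04) and PARG (-1.62) as examples. Fry tests the list's own shift and does not compare it with other genes. For the housekeeping list camera gave the direction up without passing (adjusted p = 0.859; adjusted p = 0.968 with an estimated correlation), while its median was -0.48 and its mean -0.33.

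In long genes the difference depended on the position inside the gene. In the 997 genes of 100 kb or more in FPKM quartiles 3 and 4, the share in part 1 of 10 equal parts was 80.9 ± 1.88% in HU with control siRNA (4.13 points above untreated). In part 4 it differed from untreated by -0.017 points, in part 6 by -2.54 points and in part 10 by -9.50 points (36.6 ± 0.888% against 46.1 ± 3.55%). In the 586 genes of that length and lowest FPKM it was 58.6 ± 1.31% with HU and 59.6 ± 1.54% without in part 1, and 40.7 ± 0.903% and 42.1 ± 2.13% in part 10. Over all 6 HU libraries the share in the last 10 kb of all genes was different from untreated by -4.25 ± 1.58 points (exact p = 0.0357; lower in 6 of 6 libraries). That after the gene end differed by -2.16 ± 0.472 points (exact p = 0.0357). Both exact p-values are unadjusted. Limma's fry over all genes gave an adjusted p = 0.661 for the fall at gene ends (over 16 tests). The 1876 calls became 42 without replicate 1 and 405 without replicate 2 of HU with control siRNA, 373 without untreated replicate 2 and 1137 without either FANCD2 library; with the replicate number as a block 3427 passed. HU and a longer EdU pulse (4 min against 2 min) go together in these libraries, so the difference cannot be given to HU alone.

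**Figure D3:**
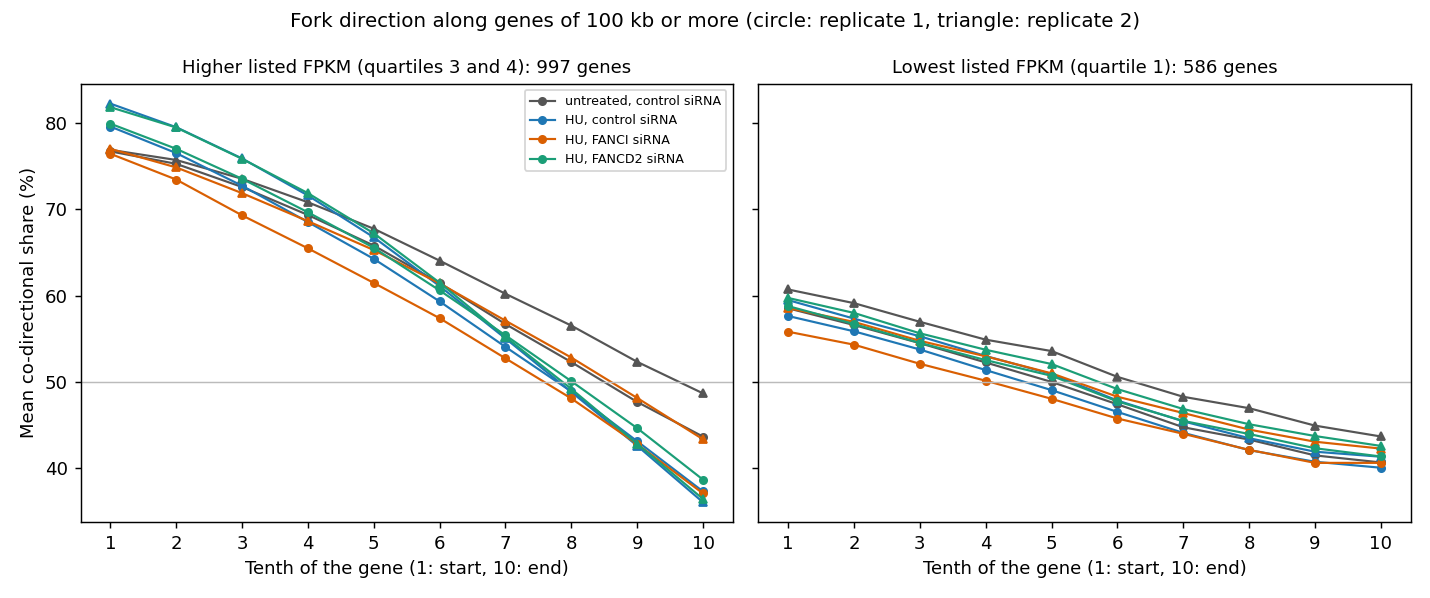
Co-directional share in percent (y axis) in 10 equal parts of genes of 100 kb or more, from the TSS to the gene end (x axis), per library, for genes of high (997 genes, left) and of lowest FPKM (586 genes, right). Mean shares in part 10 of the high-FPKM genes were 46.1% untreated, 36.6% in HU with control siRNA, 40.2% with FANCI siRNA and 37.5% with FANCD2 siRNA.

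Between the 10 kb windows on each side, the step at annotated gene ends rose with HU at most genes that passed. Within these windows this means less net termination or more net initiation, but not over a wider span. The share pooled over genes was 52.4% untreated and 51.4% in HU with control siRNA 40 to 50 kb before the gene end. From 1 to 10 kb after it the shares were 48.5% and 45.2%, so the wider mean drop was larger with HU (not tested). The largest rises of the step were at CCZ1 (3.73, SE 0.81, adjusted p = 0.035), at STAP1, an adaptor of B cell signalling (3.0, SE 0.53, adjusted p = 0.0167), and at the transporter gene SLC22A10 (2.90, SE 0.50, adjusted p = 0.0164). The falls were led by ERV3-1 (-2.92, SE 0.59, adjusted p = 0.0279), CCDC168 (-2.74, SE 0.53, adjusted p = 0.0242) and ALMS1, a protein of the ciliary base (-2.67, SE 0.51, adjusted p = 0.0242). ERV3-1 ends at the TSS of ZNF117, so these calls describe the same site. By limma 120 of 11940 genes rose and 33 fell. Of the 38 mesenchymal genes the cyclin gene CCND1 rose (1.66, SE 0.38, adjusted p = 0.035; 3 over the list alone). Of the 10 origin genes the chaperone gene HSPA4 rose (1.93, SE 0.46, adjusted p = 0.0459; 1 over the list alone). Genes of 300 kb or more gave 3 rises of 484 (2 over the list alone): KIF26B (2.34, adjusted p = 0.0167), HPSE2 (1.82, adjusted p = 0.035) and WBSCR17 (1.63, adjusted p = 0.0389). Limma called 0 fragile-site genes (6 at an unadjusted p under 0.05), 0 housekeeping genes (7), 0 lineage-restricted genes (6) and 0 replication and damage response genes (13), with 0, 0, 0 and 1 over each list alone. FHIT had 0.33 (adjusted p = 0.68) and LMNB2 -0.32 (adjusted p = 0.651). The mean end step was -1.99 ± 0.794 points in HU with control siRNA, a difference of 2.27 ± 1.23 points from untreated (exact p = 0.333, the smallest possible) and of 2.09 ± 1.16 points over all 6 HU libraries (exact p = 0.0714). The 153 calls became 0 and 12 without replicate 1 or 2 of HU with control siRNA, 76 without untreated replicate 2, 10 without either FANCD2 library, 587 without untreated replicate 1 and 434 without either FANCI library. With the replicate number as a block 1329 genes passed, and fry passed the replication and damage response list (median 0.25, adjusted p = 0.000996). By camera, without the block, that list had adjusted p = 0.903 with an estimated correlation. Fewer than the 153 genes passed with 5 kb windows, with no variance trend or with only these groups fitted, and more passed with 20 kb windows.

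The amount of Okazaki fragments per gene, which follows how much each region was replicated in the labelled cells, changed widely with HU. It rose most at THAP10 (1.70, SE 0.18, adjusted p = 2.56e-18; 3.25-fold), FAM72A (1.59, SE 0.29, adjusted p = 4.61e-07; a gene with near-identical copies) and PUM2, an RNA-binding repressor of translation (1.44, SE 0.15, adjusted p = 3.24e-18). It fell most at ZNF184 (-1.87, SE 0.18, adjusted p = 4e-22), FRMD1 (-1.82, SE 0.25, adjusted p = 5.84e-12) and ASPG (-1.59, SE 0.19, adjusted p = 1.05e-14). Genes of common fragile sites fell almost together: 28 of 29 were lower and 1 higher (29 over the list alone; median -0.70). IMMP2L, a mitochondrial protease gene inside a fragile site (chromosome 7, 110303106 to 111202347), had -1.22 (SE 0.15, adjusted p = 1.13e-13), CDH13 -0.90, AUTS2 -0.92, PARD3B -0.89 (0.04 over the first 10 kb of the gene alone) and FHIT -0.78 (SE 0.17, adjusted p = 1.36e-05). The exception, named after its value was seen, was RORA (0.35, SE 0.14, adjusted p = 0.0198). Of these 29 genes 21 were also among the genes of 300 kb or more, of which 375 of 484 fell and 17 rose (393 over the list alone; median -0.60), as at STX8 (-1.41), NEGR1 (-1.28) and SLCO3A1 (-1.21). As sets both lists passed camera with its preset correlation, but had adjusted p = 0.831 with an estimated correlation.

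**Figure D4:**
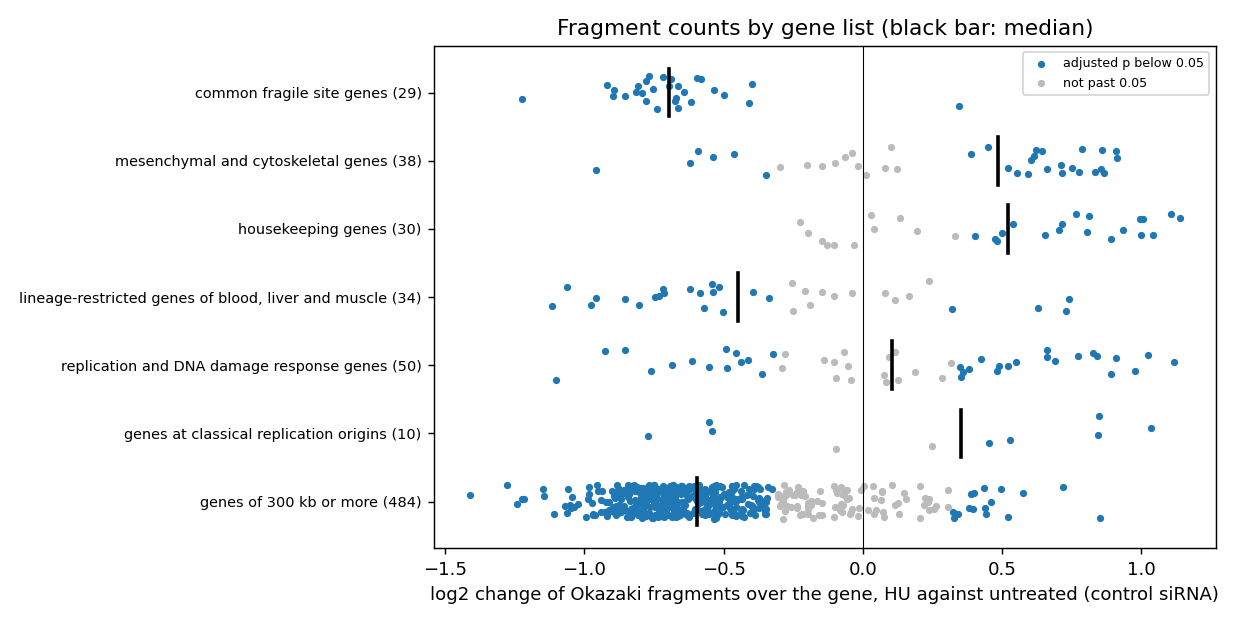
Log2 change in Okazaki fragments per gene with HU (x axis) for the members of each gene list (y axis; points, blue past adjusted p 0.05, with the list median as a bar). Medians were -0.70 for 29 fragile-site genes, -0.60 for 484 genes of 300 kb or more, -0.45 for 34 lineage-restricted genes, 0.10 for 50 replication and damage response genes, 0.35 for 10 origin genes, 0.49 for 38 mesenchymal and 0.52 for 30 housekeeping genes.

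Among housekeeping and mesenchymal genes more rose than fell relative to the median gene, but neither list passed fry (adjusted p = 0.0745 and 0.0538). By camera both had adjusted p = 0.831 with an estimated correlation. Of the 30 housekeeping genes 19 rose and 0 fell (19 over the list alone; median 0.52), such as COPB1 (1.11, SE 0.14, adjusted p = 1.34e-12), CCT3 (1.14) and SMC3 (0.99). Of the 38 mesenchymal genes 21 rose, such as SPTAN1 (0.91), LRP1 (0.87) and CAV1 (0.91), and 6 fell, such as COL5A1 (-0.96, SE 0.14, adjusted p = 1.18e-10; 27 over the list alone; median 0.49). Of the 34 genes restricted to blood, liver or muscle 19 fell, such as CPS1 (-1.06), FLT3 (-0.97) and ACTN2 (-0.96). In that list 4 rose (SPI1 0.73, MYBPC3 0.74, SLC12A3 0.63 and ITGAL 0.32, named after their values were seen; 23 over the list alone; median -0.45). The 50 replication and damage response genes went both ways (20 rose, 14 fell, 34 over the list alone; median 0.10), with SMARCAL1, a fork-remodelling ATPase (1.12, SE 0.14, adjusted p = 9.54e-14), FANCD2 (0.98) and RAD50 (0.91) higher and POLQ (-1.10) lower. Of the 10 origin genes 5 rose (AXIN1 1.04, TYRO3 0.85, TOP1 0.84, LMNB2 0.45 among them) and 3 fell, such as PRKDC (-0.77; 8 over the list alone). By FPKM quartile 47.55% of the highest rose and 19.43% fell, against 19.04% and 48.33% of the lowest; by length 42.48% of the shortest rose and 54.16% of the longest fell.

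In all, 4049 genes rose and 3933 fell of 11996 by limma, relative to the median gene. Scaled to total coverage the median gene itself stood at 0.21 (log2), 5149 genes rose and 2447 fell; the fragile-site genes then had a median of -0.48 (25 fell, 1 rose), genes of 300 kb or more -0.38 (331 fell, 44 rose) and lineage-restricted genes -0.23 (11 fell, 7 rose). Medians were 0.74 for housekeeping genes (21 rose, 0 fell), 0.70 for mesenchymal genes (23 rose, 4 fell), 0.57 for origin genes (6 rose, 2 fell) and 0.32 for replication and damage response genes (24 rose, 7 fell). Camera with its preset correlation put the fragile-site genes (adjusted p = 2.66e-07), genes of 300 kb or more (adjusted p = 1.87e-17), housekeeping genes (adjusted p = 0.000559), mesenchymal genes (adjusted p = 0.047) and lineage-restricted genes (adjusted p = 0.013) apart from other genes. Each had adjusted p = 0.831 with an estimated correlation. Fry passed no list (adjusted p = 0.0745, 0.0745, 0.0745, 0.0538 and 0.0745 in that order). For the replication and damage response list these were 0.453 by camera and 0.401 by fry. For the count, limma's p-values rest on a spread pooled over genes of the same precision (47984 degrees of freedom), not on each gene's own libraries. They treat neighbouring genes as independent, although neighbours share forks. The spread between these libraries may be technical, since the labels do not say that replicates were separate cultures.

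With FANCI siRNA under HU no gene passed against control siRNA for fork direction or steps without a replicate block, and 1 passed for the fragment count. The gene with the smallest p for the TSS step was DERA, an enzyme of deoxyribose phosphate breakdown (-1.84, SE 0.37, adjusted p = 0.512). For the end step it was the Golgi protein gene GORASP2 (-1.37, SE 0.38, adjusted p = 1) and for direction at the gene end SH3RF1 (1.25, SE 0.30, adjusted p = 0.86; 29.0% and 14.6%). In fragment count BAI1, an adhesion receptor gene listed at FPKM 0 (chromosome 8, 143545377 to 143626368), rose by 0.75 (SE 0.15, adjusted p = 0.0084; 1.68-fold). FHIT had -0.32, -0.42, 0.28 and 0.06 for TSS step, end step, end direction and count, and LMNB2 -0.48, -0.12, 0.16 and 0.27. Limma called 0 genes for the TSS step, the end step and the end direction (676, 286 and 676 at an unadjusted p under 0.05) and 1 for the count (797 unadjusted). With the replicate number as a block limma called 23 genes for the TSS step, all lower and DERA among them (adjusted p = 0.0127), and fry passed the lineage-restricted list there (adjusted p = 0.0228) and the housekeeping list for the end step (adjusted p = 0.0425). By camera, without the block, these had adjusted p = 0.215 and adjusted p = 0.903 with an estimated correlation.

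No member of a list passed over all genes with FANCI siRNA. Adjusted over the list alone, HSPA4 passed for the TSS step (-1.76, SE 0.43, adjusted p = 0.515 over all genes) and PLEC, a linker of intermediate filaments, for the count (0.63, SE 0.18, adjusted p = 0.383 over all genes); both are named after their values were seen. The TSS step of lineage-restricted genes had a median change of 0.13, against -0.13 over all genes tested. Camera with its preset correlation put this list higher than other genes (adjusted p = 0.0057, and adjusted p = 0.215 with an estimated correlation). It also put the end direction of genes of 300 kb or more higher (median 0.13, adjusted p = 0.0405; adjusted p = 0.935 with an estimated correlation). Counts were lower for housekeeping genes (median -0.07, adjusted p = 0.0475) and replication and damage response genes (median -0.10, adjusted p = 0.0322) and higher for lineage-restricted genes (median 0.10, adjusted p = 0.0215) by the same test. All 3 had adjusted p = 0.831 with an estimated correlation. Fry passed none of these; its smallest adjusted p here was that of the TSS step of mesenchymal genes (0.0567, median -0.30). The mean share after the TSS was 59.9 ± 1.43% with FANCI siRNA and 61.7 ± 1.15% with control siRNA, a difference of -1.83 ± 1.30 points (exact p = 0.333, the smallest possible). In the transcribed genes of 100 kb or more, part 1 had 76.7 ± 0.404% with FANCI siRNA and 80.9 ± 1.88% with control siRNA, a difference not tested. The mean TSS step differed by -1.12 ± 1.63 points (exact p = 1) and the share in the last 10 kb by 0.659 ± 1.91 points (exact p = 1). The BAI1 call was lost when only these groups were fitted and without replicate 1 of HU with control siRNA or either FANCI library, and 74 genes passed without replicate 2 of HU with control siRNA.

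With FANCD2 siRNA under HU no gene passed against control siRNA in any of the 4 measures. For the TSS step 1 gene passed with no variance trend, and for the end step 1 with a replicate block. The smallest p was at SESTD1 for the TSS step (-1.67, SE 0.48, adjusted p = 1) and at RWDD4 for the end step (-1.55, SE 0.45, adjusted p = 1). It was at the spliceosome gene SNRPG for the end direction (1.44, SE 0.35, adjusted p = 0.843; 18.7% and 7.75%) and at CREB3L2, a transcription factor of the secretory pathway, for the count (-0.51, SE 0.14, adjusted p = 0.999). FHIT had 0.16, -0.14, 0.15 and 0.03 in that order and LMNB2 0.05, -0.28, 0.38 and 0.04. Limma called 0 genes in the 4 measures, in that order 176, 134, 574 and 232 at an unadjusted p under 0.05, and 0 list members over all genes. Camera with its preset correlation put the end direction of the replication and damage response genes higher (median 0.32, adjusted p = 0.0191; adjusted p = 0.935 with an estimated correlation). It put the counts of that list (median -0.08, adjusted p = 0.0475) and of genes of 300 kb or more (median -0.08, adjusted p = 5.39e-05) lower. Both had adjusted p = 0.831 with an estimated correlation, and fry passed no list. With the replicate number as a block fry passed the replication and damage response list for the end step (median -0.09, adjusted p = 0.00516). By camera, without the block, it had adjusted p = 0.903 with an estimated correlation. The mean TSS step was 7.32 ± 0.0286 points, a difference of 1.24 ± 0.276 points from control siRNA (exact p = 0.333, the smallest possible), and the share in the last 10 kb differed by 0.889 ± 0.442 points (exact p = 0.333).

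Set directly against each other, FANCI and FANCD2 siRNA differed in fragment count at 3 genes, all higher with FANCI siRNA. HDAC4, a class IIa histone deacetylase (chromosome 2, 240016312 to 240098259), had 0.78 (SE 0.15, adjusted p = 0.00185). The others were GPR123, an adhesion receptor gene (0.73, SE 0.15, adjusted p = 0.00632) and KLHL29 (0.68, SE 0.14, adjusted p = 0.00632). The genes with the smallest p in the other measures were FLI1 for the TSS step (-1.53, SE 0.38, adjusted p = 0.898) and PIK3C3, a lipid kinase of autophagy, for the end step (1.43, SE 0.42, adjusted p = 0.999). For the end direction it was TRAK1, an adaptor of mitochondrial transport (1.51, SE 0.35, adjusted p = 0.998; 81.2% and 60.1%). FHIT had -0.48, -0.28, 0.13 and 0.03 and LMNB2 -0.52, 0.17, -0.22 and 0.23. Limma called 0 genes for the TSS step, end step and end direction (605, 266 and 448 at an unadjusted p under 0.05) and 3 for the count (932 unadjusted), none of them a list member. The TSS step of lineage-restricted genes had a median change of 0.03, against -0.19 over all genes tested. Camera, which compares a list with other genes, put this list higher at its preset correlation (adjusted p = 0.00126, and adjusted p = 0.215 with an estimated correlation). It also put the end direction of mesenchymal genes higher (median 0.25, adjusted p = 0.0191; adjusted p = 0.935 with an estimated correlation). The counts of genes of 300 kb or more were higher as well (median 0.10, adjusted p = 5.39e-05; adjusted p = 0.831 with an estimated correlation). Fry passed no list, except with the replicate number as a block (lineage-restricted genes for the TSS step, adjusted p = 0.0297; housekeeping genes, adjusted p = 0.0392, and replication and damage response genes, adjusted p = 0.00408, for the end step). By camera, without the block, these had adjusted p = 0.215, 0.903 and 0.903 with an estimated correlation. The mean TSS step differed by -2.35 ± 1.61 points and the share after the TSS by -2.79 ± 1.14 points (both exact p = 0.333, the smallest possible). Of the count calls 0 were left without either FANCI library or FANCD2 replicate 2, 13 genes passed without FANCD2 replicate 1, and 15 when only these groups were fitted.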

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

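Precision weights, a fit with no variance trend, masked extreme bins, crossed replicate numbers and counts scaled to total coverage were chosen after seeing the data. Of the comparison values under all settings 520 held, 89 moved, 4 newly passed and 7 no longer passed. Of those of named genes and lists 3481 held, 92 newly passed and 318 no longer passed. Values that passed under neither setting counted as held, also where their sign changed. Counts of calls held where they were equal or within a fixed ratio, and mean differences where they stayed within the spread of replicates. Many of the values that held are therefore absent calls in both settings. A reversal was counted only where a value passed under either setting. PARD3B reversed, with a count change with HU of 0.04 over the first 10 kb of the gene. The cause was not tested for any of the changes below, except that longer genes and left-out libraries leave fewer genes or samples.

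With the replicate number as a block (replicate block), HU against untreated gave 1409 genes for the TSS step (583 rose, 826 fell), 1329 for the end step (969 rose, 360 fell) and 3427 for the direction at gene ends (499 rose, 2928 fell). FANCI against control siRNA gave 23 genes for the TSS step, all lower, and FANCD2 against control siRNA 1 for the end step. Among the lists 3 fry calls were made for the TSS step, all of the lineage-restricted genes, and 5 for the end step. Deviations of replicates from their group mean correlated by replicate number among untreated, HU with control siRNA and FANCI siRNA (0.226, 0.313 and 0.337 for the TSS step, 0.205, 0.426 and 0.273 for the direction). Those of FANCD2 siRNA with these groups did so at -0.012 to 0.03 for the TSS step, and for the direction at 0.272 with untreated, 0.291 with HU with control siRNA and 0.046 with FANCI siRNA, and for the count untreated and HU with control siRNA at -0.331. With replicate numbers crossed between the groups, the count gave 8203 genes for HU against untreated and 3 for FANCI against FANCD2 siRNA.

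For the TSS step with HU (277 genes), 129 passed with only these groups fitted, 110 after thinning to equal depth, 0 with 5 kb and 1089 with 20 kb windows, 454 with precision weights and 0 with no variance trend. For the end step (153 genes) these were 53, 81, 24, 653, 395 and 27, and 87 in genes of 30 kb or more. For the direction (1876 genes) thinning gave 1247 and no variance trend 1146. For the count (7982 genes) genes of 30 kb or more gave 4682. FANCD2 siRNA had 1 TSS step call with no variance trend. The count call of FANCI against control siRNA went to 0 with only these groups fitted, in genes of 30 kb or more, after thinning and over the first 10 kb of the gene. The 3 count calls of FANCI against FANCD2 siRNA became 15 with only these groups fitted, 5 after thinning, 1 over the first 10 kb and 0 with no variance trend. Camera with its preset correlation made 2 list calls for the TSS step, 4 for the direction and 11 for the count where fry made 0, and 0 in every measure with an estimated correlation. With at most 1 gene per 500 kb fry made 1 for the count. Fewer genes thus passed at equal, lower depth for the steps and the direction.

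The upstream difference of HU from untreated (2.18 points) was 3.89 with 5 kb and 0.976 with 20 kb windows, 3.21 with pooled reads and 3.27 in genes of 30 kb or more. Over all 6 HU libraries it was 0.792 with 20 kb windows (exact p = 0.107). For FANCI siRNA it was -1.49 against control and -1.13 against FANCD2 siRNA with 5 kb windows. After the TSS, HU gave 1.54 points in genes of 30 kb or more, and FANCI against control siRNA -3.19 with pooled reads. The TSS step difference with HU was -3.77 points with 5 kb windows (-3.45 over 6 HU libraries, exact p = 0.0357). After the gene end it was -3.18 with 5 kb windows, -3.64 at genes with no other gene within 10 kb, -3.52 with pooled reads and -3.80 in genes of 30 kb or more.

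Leaving out each library in turn, the lone library left was taken to vary like the other groups. For HU against untreated this gave 0 to 554 genes for the TSS step, 0 to 587 for the end step, 42 to 2730 for the direction and 5861 to 8166 for the count. The lowest were without a library of HU with control siRNA for the steps and direction. The highest were without a FANCI library (TSS step) and without untreated replicate 1 (end step). The count gave 0 to 74 genes for FANCI against control siRNA (74 without replicate 2 of HU with control siRNA) and 0 to 13 for FANCI against FANCD2 siRNA (13 without FANCD2 replicate 1). Mean differences of FANCI against control siRNA ran from -2.73 to 0.495 points for the TSS step, -1.21 to 2.53 for the last 10 kb and 0.119 to 1.58 after the gene end. Against FANCD2 siRNA they ran from -3.97 to -0.743, -2.10 to 1.64 and -0.0240 to 1.43. For 6 HU libraries against untreated they ran from 1.67 to 2.04 upstream, -5.74 to -2.76 in the last 10 kb and -2.56 to -1.76 after the gene end. Without an untreated library the smallest exact p is 0.143. The end step ran from 0.995 to 3.18 (exact p = 0.0476 without replicate 1 of HU with control siRNA, FANCI replicate 1 or FANCD2 replicate 2).

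Of the alternatives fixed beforehand, the other count-model test and its size factors were not run because the values are coverage, limma became the test itself, all values are autosomal, and strand totals cancel in the steps.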

Other observations

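The search for steps across the genome, the exchange of untreated replicates, the test of thinning at gene ends and the replicate order by scale position and in part 10 were chosen after the result was seen. Steps of 30 points or more between neighbouring 20 kb windows, after thinning to equal depth, gave 3929 and 7602 initiation sites in the untreated libraries and 4445 and 5176 in HU with control siRNA. Of these 29.6% and 19.6% lay within 20 kb of the TSS of a gene in FPKM quartiles 3 or 4 in untreated cells, and 37.9% and 35.3% in HU with control siRNA. With FANCI siRNA it was 38.8% and 37.4%, and with FANCD2 siRNA 36.9% and 34.5%, against 9.93% of all positions. With steps of 40 points or more the shares were 44.8% and 23.6% in untreated cells and 46.4% and 46.3% in HU with control siRNA, so untreated replicate 1 then lay close to the HU libraries.

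Termination sites were fewer: 2102 and 6716 in untreated cells, 497 and 2150 in HU with control siRNA, 273 and 1393 with FANCI siRNA and 1543 and 2081 with FANCD2 siRNA. Within 20 kb of the end of a gene of FPKM quartiles 3 or 4 lay 8.66% and 9.34% of those in untreated cells and 38.8% and 21.1% in HU with control siRNA. With FANCI siRNA it was 50.2% and 12.8% and with FANCD2 siRNA 20.9% and 22.1%, against 9.66% of all positions. Initiation sites near these ends had mean shares of 9.92% untreated and 21.1% in HU with control siRNA. They were 19.9% with FANCI siRNA and 18.9% with FANCD2 siRNA, so higher shares there were not particular to termination. The mean number of termination sites was lower in HU with control siRNA (1324 against 4409), so a higher share does not mean more such sites. Genes of the highest FPKM were parted by DRIP-seq signal at the TSS, above their median or not (1462 each). The mean TSS steps of those above were 9.89 and 13.2 points in the untreated libraries, 8.40 and 8.64 in HU with control siRNA, 4.89 and 9.52 with FANCI siRNA and 10.4 and 10.1 with FANCD2 siRNA. Those of the others were 9.78 and 12.2, 9.03 and 9.19, 5.44 and 9.30, and 10.5 and 10.4 points, so which set had the larger step differed between groups.

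The share of co-directional forks at gene ends fell with HU, and lower strand contrast of the HU libraries would move genes under 40% towards 50%. Genes under 40% in untreated replicate 1 (4201) instead had a median log2 change of -0.87 from untreated replicate 2 to HU with control siRNA. It was -0.23 with the untreated replicates exchanged, so its size depends on the replicate. Untreated replicate 2 had lower strand contrast than both libraries of HU with control siRNA. A change measured from that replicate therefore leans away from 50%, and the smaller value is the fairer test. Genes over 60% changed by -0.04 and -0.22 in the same order. Strand contrast (SD of the strand bias over 50 kb windows) was 0.452 and 0.401 untreated and 0.450 and 0.436 in HU with control siRNA. It was 0.392 to 0.416 with FANCI or FANCD2 siRNA. For HU with control siRNA these values argue against lower contrast. At equal depth 1143 of 1876 genes stayed past the threshold. Thinning leaves the expected share of genes with many reads as it is, so this cannot decide on unequal depth. The EdU pulse stays open, since 0 HU libraries had the pulse of the untreated cells. Forks from the TSS that reach less far into the gene stay open too. In transcribed genes of 100 kb or more the change in part 6 minus that in part 1 was -6.67 points, which met the limit fixed beforehand for this explanation. This difference holds a rise of 4.13 points in part 1, and whether shorter reach would give that rise was not tested. A demand on the change of part 6 itself, which was -2.54 points, was added later and was not met.

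Of 484 genes of 300 kb or more 375 had fewer fragments with HU. A few extreme bins are argued against by a median of -0.60 with these bins masked, against -0.60 as measured. After thinning to equal depth the median was -0.60 too. Thinning leaves the expected change of genes with many reads as it is, so this cannot decide on unequal depth. Whether the gene itself or its wider region sets the change stays open: windows 100 to 300 kb outside these genes changed by 62.5% of the genes' median (-0.37 and -0.60), and for fragile-site genes by 85.6%. The changes of genes and windows correlated (Pearson r 0.66 for genes of 300 kb or more, 0.46 for fragile-site genes and 0.80 over all genes), so part of the change was shared with the region.

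FANCI replicate 2 lay between the untreated and the other HU libraries at gene ends, at 53.1 on a scale from untreated (0) to FANCD2 siRNA (100). Strand contrast was lower in replicate 2 than in replicate 1 of every group, so low contrast was not particular to this library. Low strand contrast stays open for FANCI replicate 2, as its SD over 50 kb windows was 0.397, with FANCD2 replicate 2 lower at 0.392. So does a weaker response to HU, as its position by fragment counts was 80.2, with 91.4 to 107 for the other HU libraries. A difference that follows the replicate number stays open as well. Replicate 2 had a higher mean share at gene ends by 0.81 points in HU with control siRNA and 0.36 with FANCD2 siRNA (3.74 with FANCI siRNA, 2.98 untreated). By this measure the condition fixed beforehand for a replicate effect was met. Of the measures chosen later, on the scale above FANCD2 replicate 2 lay farther from untreated (108) than replicate 1 (92.2). Part 10 of long transcribed genes was also lower in replicate 2 of HU with control siRNA (36.0 and 37.3%) and FANCD2 siRNA (36.4 and 38.6%). No biological explanation was tested for this library.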
